A study of Homo sapiens with 18 samples.

How the data were processed

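Total RNA of HCC827 cells in 18 samples was turned into biotinylated complementary RNA and hybridized to Illumina bead arrays, per the labels; the scanner and software were not given in the sources used here. The deposited table holds 47323 probes by 18 arrays in linear intensity units that the authors had not log transformed, and its array medians and ranges differ between arrays, so it was read as not normalized between arrays. Detection p-values and control probes were not used here, so detection was not assessed.

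The design written before the data were examined assumed a table normalized by the authors, with a floor at the 5th percentile and log2. Because the deposited intensities were not, the values were corrected for background with limma normexp (offset 50), put on the log2 scale and quantile normalized over the 18 arrays with limma 3.58.1 in R 4.3.3; the floor and log2 transformation without normalization is given as an alternative. The 2 probes with a value of 0 (3 values) were left out, leaving 47321. Probe symbols came from the platform annotation: 30121 probes were listed, 30113 with 1 symbol and 8 with several, and 17202 were not listed. Symbols were compared by Entrez identifier with a RefSeq table of the human assembly GRCh38.p14 (30074 probes matched, 0 symbols changed); genome positions were not used here. Each gene was represented by its probe with the highest mean over all arrays (6691 genes had several), giving 20046 genes. Probes without a single symbol (17208) were tested apart.

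One limma model with 6 group means (residual degrees of freedom 12), empirical Bayes moderation with an intensity trend and Benjamini-Hochberg adjustment over all genes gave 5 comparisons of 2 groups and 3 differences of effects. A gene was called at an adjusted p below 0.05, and all tests are two-sided. The 26 gene lists (607 symbols, 567 measured) were written before the data were examined; each was tested with limma camera (preset correlation 0.01, adjusted over the 26 lists), again with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. Calls are also counted with adjustment over the list alone. The lists cover epithelial junctions, epithelial identity and keratins, mesenchymal cytoskeleton and adhesion, EMT transcription factors, extracellular matrix, matrix proteases and inhibitors, TGF-beta/SMAD targets, beta-catenin/TCF targets, ERBB receptors and ligands, ERK pathway output, bypass receptor kinases and ligands, the BCL2 family, YAP/TEAD targets, lung epithelial differentiation, proliferation, interferon response, MHC class I presentation, NF-kB and inflammatory cytokines, unfolded protein and amino acid stress, hypoxia and glycolysis, sterol and fatty acid synthesis, NRF2 targets, and markers of haematopoietic, endothelial and neuroendocrine cells and reference transcripts. Some genes stand in several lists.

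Named genes followed a rule also written before the data were examined: CDH1, SNAI1 and VIM always; in each main comparison the 10 largest rises and the 10 largest falls among called genes whose 3 arrays of one group all lay on one side of the other 3, without unnamed reading frames; up to 4 called members of each list with the largest change; and, across comparisons, the 10 largest shared and the 10 largest opposite changes. The text names a part of these.

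Replicate numbers were not used to pair arrays across groups in the main model. Within a comparison, the deviations of equally numbered arrays from their group means correlated across genes at -0.19 to 0.33. All were positive except number 1 of the shCDH1 comparison. Unequally numbered arrays were not compared, so these values cannot decide whether the numbers pair arrays. The closest 2 arrays of a group were numbers 1 and 2 in 2 of 6 groups (exact binomial p = 1). The number of arrays, 3 per group, limits the precision. In data simulated with the same spread, with 200 of 20046 genes changed, 179, 183 and 193 genes were called in the 3 main comparisons and 7, 12 and 12 of these calls were false. A change of 1 log2 unit was called for 96%, 94% and 98% of genes, and one of 0.5 for 48%, 48% and 64%. The simulation drew genes independently after normalization and changed far fewer genes than were called in the real data. Its shares therefore need not hold for these arrays.

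Alternatives were other filters on low signal, median centring, no normalization, other probe rules, other moderation, replicate and description numbers as blocks or averaged, other control groups, other floors and offsets, a size threshold, the 6 arrays of a comparison alone, and each array left out in turn. Other splits of the samples were counted for every comparison.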

Results

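Messenger RNA was profiled on Illumina bead arrays in HCC827, a human lung adenocarcinoma cell line with a mutant EGFR gene. The 18 arrays form 6 groups of 3. Parental cells and cells given the growth factor TGFB1 make up the first comparison. Cells with a lentivirus for the transcription factor SNAIL (gene symbol SNAI1) have lacZ virus cells as control, and cells with a short hairpin RNA against CDH1, the gene of E-cadherin (shCDH1), have non-target hairpin cells (shNT) as control. The titles name the vector pLX303 for the lacZ and SNAIL-V5 cells and pLKO1 for the shNT and shCDH1 cells. The series concerns epithelial to mesenchymal transition (EMT), the loss of epithelial adhesion and gain of mesenchymal traits. Sample labels give 30 days of TGFB1, while the series text gives 72 hours at 10 ng/mL, and nothing in the arrays settles which. Titles number the arrays of a group 1 to 3 and descriptions number them 1, 1 and 2, and neither says that they come from separate cultures, so the p-values below measure a spread that may be technical.

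Median intensity per array ran from 152 to 236, and the highest intensity from 15951 to 20729. Across probes, arrays of one group correlated at r = 0.989 to 0.994 and arrays of different groups at 0.930 to 0.989, and all 18 arrays were closest to an array of their own group. Levels are normalized log2 intensities. Changes are folds or log2 differences ± SE with 3 arrays per group, and the median SE of a log2 difference was 0.128. A fold with one group below the array-wide median of 6.82 rests on signal near background, so its size varies with the background correction and the probes used. Every fold rests on a single probe per gene, and its SE leaves out the choice of probe, scaling and control.

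CDH1 was the gene aimed at by the hairpin. Its level (probe ILMN_1770940, mean ± SD, n = 3) was 13.00 ± 0.06 in shNT and 8.60 ± 0.40 in shCDH1 cells, a 21.1-fold loss, and it went from 13.12 ± 0.03 in lacZ to 7.50 ± 0.04 in SNAIL cells, a 49-fold loss. Under TGFB1 it went from 13.03 ± 0.03 to 12.69 ± 0.09 (log2 difference -0.35 ± 0.12, adjusted p = 0.0317). That call ended with median centring (adjusted p = 0.155), with arrays sharing a description number averaged (0.115) and without the variance trend (0.0511). It also ended with any one of parental arrays 1, 2 and 3 or TGFB1 arrays 2 and 3 left out (adjusted p from 0.0588 to 0.115). VIM, which encodes the mesenchymal intermediate filament vimentin (ILMN_1782538), rose 7.95-fold under TGFB1 and 7.46-fold in shCDH1 cells. In lacZ cells VIM already stood at 12.86 ± 0.04 against 10.27 ± 0.08 in parental cells, and SNAIL cells reached 13.35 ± 0.05, a 1.41-fold rise. This last call ended without normalization between arrays (adjusted p = 0.118) and with a floor and log2 alone (adjusted p = 0.137). CDH2, which encodes N-cadherin (ILMN_1779228), was also raised in lacZ cells, with levels of 6.36 ± 0.08 in parental, 11.16 ± 0.09 in TGFB1, 10.56 ± 0.12 in lacZ, 11.46 ± 0.02 in SNAIL, 8.17 ± 0.12 in shNT and 12.82 ± 0.08 in shCDH1 cells. Its log2 difference between SNAIL and lacZ, 0.90, falls outside the rule for named genes and was chosen after its value was seen. The SNAI1 probe (ILMN_1758086) had group means between 6.14 and 6.50, with a log2 difference of -0.14 ± 0.14 in SNAIL cells (adjusted p = 0.528) and 0.32 ± 0.14 under TGFB1 (adjusted p = 0.096).

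**Figure D1:**
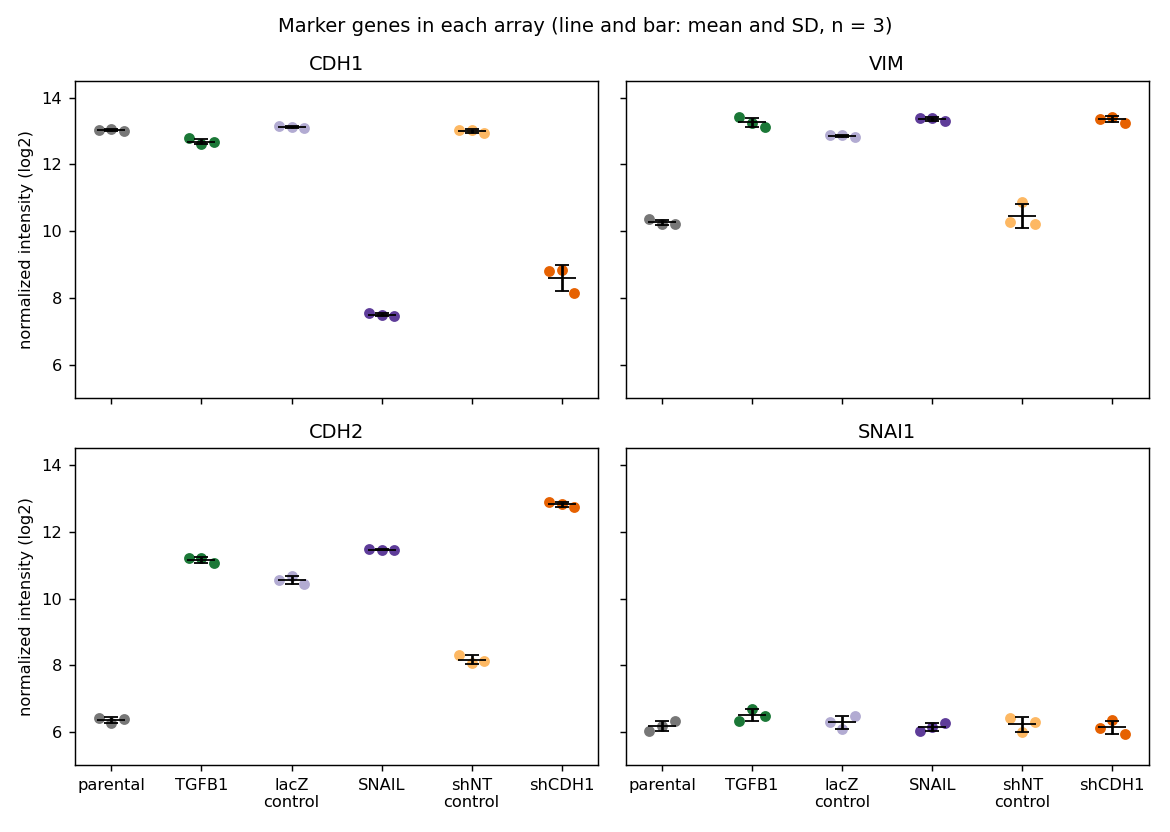
Normalized log2 intensity (y axis) of CDH1, VIM, CDH2 and SNAI1 in each of the 18 arrays, by group (x axis); points are arrays, lines and bars the mean and SD of 3 arrays. CDH1 is near 13 except in the SNAIL (7.50) and shCDH1 (8.60) groups, VIM and CDH2 are already high in the lacZ group, and the group means of SNAI1 lie between 6.14 and 6.50.

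TGFB1 against parental cells asks what the growth factor changed. Of the 10 largest rises, that of ADAM19, a membrane metalloprotease, was 94.5-fold (log2 6.56 ± 0.15), COL5A1, a fibrillar collagen chain, 73.9-fold, and HTRA1, a secreted serine protease, 48-fold. Over the alternatives the log2 change of ADAM19 ran from 3.28 to 7.26. The cytokine gene IL11 rose 50.8-fold, the atypical chemokine receptor gene ACKR3 80.3-fold, SRPX 74.7-fold and CALB2, which encodes the calcium-binding protein calretinin, 63.3-fold. Of the 10 largest falls, that of TSPAN8, a tetraspanin, was 92.5-fold (log2 -6.53 ± 0.12), NAPSA, a protease of alveolar type II cells, 89.6-fold, the adhesion gene CEACAM6 73.7-fold and SCNN1A, a subunit of the epithelial sodium channel, 45.9-fold. The transcription factor gene SOX2 fell 51.7-fold and the mucin gene MUC1 38.1-fold. Of 20046 genes tested, 6245 were called (31.2%), 3098 higher and 3147 lower, and 1460 of them changed by at least 1 log2 unit. Without normalization between arrays the median of all genes shifted by -0.22 (-0.28 with a floor and log2 alone), and the share of called genes that were higher went from 49.6% to 17.0% (13.1%), so directions here are relative to the bulk of genes. TGFB1 arrays 1 and 2 had the lowest median intensities of all arrays (154 and 152). TGFB1 array 3 (225) lay within the parental range of 186 to 236. Whether the dim arrays alone made the shift was not tested.

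Epithelial programmes fell under TGFB1. In the epithelial identity and keratin list, 1 rose, 26 fell and 9 were not called (1 higher and 26 lower adjusted over the list alone; camera adjusted p = 6.16e-17). RAB25, a small GTPase of epithelial trafficking, fell 31.9-fold. Of the 23 junction genes, 3 rose, 14 fell and 6 were not called (3 higher and 17 lower adjusted over the list alone; camera adjusted p = 7.27e-05), with CLDN3 down 2.75-fold and CLDN1 up 3.12-fold, both tight junction claudins. Mesenchymal cytoskeleton and adhesion genes rose as a group: of 31, 21 rose, 2 fell and 8 were not called (22 higher and 2 lower adjusted over the list alone; camera adjusted p = 7.78e-14), led by CDH2 (28-fold) and GLIPR1 (19-fold). Among 19 EMT transcription factors, 10 rose, 1 fell and 8 were not called (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000107). SNAI2 rose 7.85-fold and ZEB2 5.15-fold, both repressors of CDH1, but against lacZ cells SNAI2 did not pass (log2 0.051, adjusted p = 0.843). A dimmer ZEB2 probe (ILMN_1820767) had levels of 6.37 ± 0.27 in parental and 6.46 ± 0.14 in TGFB1 cells, below the array-wide median. Extracellular matrix genes followed, with 35 measured, of which 22 rose, 3 fell and 10 were not called (22 higher and 3 lower adjusted over the list alone; camera adjusted p = 5.14e-13), among them the proteoglycan gene BGN (28.8-fold). For matrix proteases and inhibitors, 13 rose, 3 fell and 4 were not called (13 higher and 3 lower adjusted over the list alone; camera adjusted p = 1.25e-05). The gelatinase gene MMP9 rose 30.6-fold and the matrilysin gene MMP7 fell 25.9-fold. Lung epithelial differentiation genes went down, as 2 rose, 7 fell and 15 were not called (2 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0108), and the surfactant transporter gene ABCA3 rose 4.17-fold. That call ended with genes above the median probe alone (adjusted p = 0.0729) and against all 3 control groups (median -0.042, adjusted p = 0.246). HOPX, a marker of alveolar type I cells, fell 10.9-fold (log2 -3.44). Its log2 change was -0.27 (adjusted p = 0.488) with offset 16, -0.29 (adjusted p = 0.146) against shNT cells and 0.37 (adjusted p = 0.0705) against lacZ cells.

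Signalling targets moved too. Of 33 TGF-beta/SMAD targets, 22 rose, 4 fell and 7 were not called (22 higher and 4 lower adjusted over the list alone; camera adjusted p = 2.17e-10), and the feedback inhibitor PMEPA1 rose 12.8-fold and ANGPTL4 8.45-fold. Of 23 YAP/TEAD targets, 15 rose, 1 fell and 7 were not called (17 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.55e-07). CCN2, which encodes connective tissue growth factor, rose 6.89-fold and IGFBP3, an IGF binding protein, fell 5.46-fold. Beta-catenin/TCF targets rose by the preset test (8 rose, 3 fell and 8 were not called, or 8 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0322; adjusted p = 0.0927 with an estimated correlation), with TNFRSF19 up 5.71-fold and the Wnt inhibitor NKD2 up 4.93-fold. In the NF-kB and cytokine list, 14 rose, 5 fell and 7 were not called (14 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.000195). The monocyte chemokine CCL2 rose 32.8-fold, IL6 23.6-fold, and the chemokine CCL20 fell 4.2-fold, though against lacZ cells CCL20 was higher (log2 0.90, adjusted p = 1.37e-07). Unfolded protein and amino acid stress genes rose (12 rose, 1 fell and 11 were not called, or 14 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000256), PHGDH of serine synthesis by 4.1-fold, while the chaperone gene PDIA4 fell 2.03-fold. Against lacZ cells neither passed (PHGDH log2 0.14, adjusted p = 0.279; PDIA4 -0.22, adjusted p = 0.221). Proliferation genes fell by the preset test (3 rose, 13 fell and 24 were not called, or 3 higher and 15 lower adjusted over the list alone, camera adjusted p = 0.0031; adjusted p = 0.0927 with an estimated correlation). That call also ended against shNT cells (median -0.022, adjusted p = 0.944) and against all 3 control groups (-0.066, adjusted p = 0.131). The replication licensing gene CDC6 fell 1.87-fold and cyclin E1, CCNE1, rose 1.91-fold (not called without normalization, adjusted p = 0.0599, or with the floor, adjusted p = 0.131). With a floor and log2 alone, the medians of the EMT factor, beta-catenin and stress lists turned from 0.39, 0.18 and 0.37 to -0.09, -0.19 and -0.06, against the all-gene median of -0.28.

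Interferon response genes were lower under TGFB1 than in parental cells, as 1 rose, 31 fell and 4 were not called (1 higher and 32 lower adjusted over the list alone; camera adjusted p = 7.78e-14). IFITM1 fell 5.04-fold and the antiviral GTPase MX2 4.56-fold, while IFI6 rose 4.52-fold, though another IFI6 probe was called the opposite way. Against lacZ cells IFITM1 and MX2 were higher (log2 1.60 and 1.25). Against shNT cells MX2 was higher (0.61) and IFITM1 did not pass (-0.14, adjusted p = 0.586). For antigen presentation by MHC class I, 0 rose, 9 fell and 5 were not called (0 higher and 9 lower adjusted over the list alone; camera adjusted p = 7.27e-05). The immunoproteasome gene PSMB8 fell 2.68-fold and HLA-B 1.98-fold, while HLA-B was higher than in lacZ (log2 0.75) and shNT cells (1.02). The direction depends on the control: the interferon median of -0.75 against parental cells was 0.63 against lacZ cells (adjusted p = 2.48e-10) and 0.62 against shNT cells (adjusted p = 3.82e-06). For MHC class I the medians against lacZ and shNT cells were 0.09 (adjusted p = 0.739) and 0.03 (adjusted p = 0.652), and for lung differentiation 0.06 (adjusted p = 0.739) and -0.03 (adjusted p = 0.592).

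Of the 15 lists that camera called under TGFB1, 13 kept their calls with an estimated correlation. The remaining lists passed no camera test. In ERBB receptors and ligands, 4 rose, 5 fell and 6 were not called (5 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.872). HBEGF, a ligand of EGFR, rose 4.7-fold, the receptor gene ERBB3 fell 4.25-fold, and the list's median was 0.13 but its mean -0.10 and its test pointed down. For output genes of the ERK pathway, 6 rose, 9 fell and 7 were not called (6 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.352), with the ephrin receptor EPHA4 up 5.32-fold and the feedback inhibitor SPRY1 down 5.03-fold. Bypass receptor kinases and ligands split, as 9 rose, 11 fell and 13 were not called (10 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.449). GAS6, the ligand of AXL, rose 7.23-fold and FGFBP1, a carrier of FGF, fell 11.7-fold. Of the BCL2 family, 7 rose, 3 fell and 6 were not called (7 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.352), including the pro-apoptotic members BIK (2.05-fold up) and BOK (1.86-fold up; adjusted p = 0.195 with the floor). Hypoxia and glycolysis gave 8 rose, 2 fell and 9 were not called (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0528), with VEGFA, a vessel growth factor, up 1.87-fold (adjusted p = 0.0564 without normalization and 0.137 with the floor). The list passed without parental array 1 or 2 or TGFB1 array 3 (adjusted p from 0.0248 to 0.0347). Sterol and fatty acid synthesis gave 3 rose, 6 fell and 10 were not called (3 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.109). SREBF1, a regulator of the pathway, fell 3.15-fold and HMGCS1, an enzyme of it, 1.68-fold. The sterol list passed the camera test with median centring (median -0.24, adjusted p = 0.0459) and against all 3 control groups (-0.18, adjusted p = 0.0149). It also passed against lacZ cells (median -0.42). NRF2 targets gave 4 rose, 6 fell and 4 were not called (6 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.38), with the efflux transporters ABCC2 and ABCC3 down 14.6-fold and 12.4-fold, the aldo-keto reductase AKR1C2 up 5.01-fold, a median of 0.06, and a mean of -0.38 with the test pointing down.

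Markers of other cell types passed no list test either. Haematopoietic markers gave 4 rose, 2 fell and 8 were not called (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.64). CD14 fell 2.83-fold and FCER1G rose 2.57-fold, while CD14 was not called against lacZ cells (log2 0.11, adjusted p = 0.601). Endothelial markers gave 4 rose, 0 fell and 6 were not called (5 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.206), with PECAM1 up 1.69-fold and ESAM up 1.52-fold (adjusted p = 0.065 without parental array 3) from levels below the array median. With the floor neither passed (PECAM1 log2 0.11, adjusted p = 0.569; ESAM 0.0043, adjusted p = 0.983). Neuroendocrine markers gave 2 rose, 0 fell and 7 were not called (2 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.449). DLL3 rose 2.6-fold and SCG3 1.42-fold (adjusted p = 0.052 without parental array 1; log2 -0.042, adjusted p = 0.82, with the floor). Reference transcripts gave 0 rose, 1 fell and 11 were not called (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.486), the one gene being GUSB (1.21-fold down). The GUSB call ended with any one of parental arrays 1, 2 and 3 or TGFB1 arrays 2 and 3 left out (adjusted p from 0.0624 to 0.166).

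SNAIL against lacZ cells asks what the virus for this EMT transcription factor changed, though the arrays do not show a higher SNAI1 level. Among the 10 largest falls, KRT19, a keratin of simple epithelia, fell 119-fold (log2 -6.90 ± 0.09), MAL2, a protein of apical transport, 100-fold, ERP27, a protein of the endoplasmic reticulum, 101-fold, and LCN2, the secreted lipocalin, 64.4-fold. SPP1, which encodes osteopontin, fell 73.6-fold, from a lacZ level that was itself above the parental one. Among the 10 largest rises, COL3A1, a fibrillar collagen, rose 93.6-fold (log2 6.55 ± 0.12), SPARC, a collagen-binding protein, 75.8-fold, and BGN 66.7-fold. FST, which encodes the activin inhibitor follistatin, rose 57.8-fold and PLAC8 81.7-fold. Of 20046 genes, 7340 were called (36.6%), 3927 higher and 3413 lower, and 2029 changed by at least 1 log2 unit; the share higher was 53.5%, and 43.3% of 3599 with a floor and log2 alone.

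The junction list fell almost in full after SNAIL, as 0 rose, 21 fell and 2 were not called (0 higher and 22 lower adjusted over the list alone; camera adjusted p = 1.07e-20). EPCAM, an epithelial adhesion molecule, fell 57-fold, cingulin, CGN, 23.5-fold and CLDN7 18.8-fold. Epithelial identity and keratin genes fell with it (0 rose, 30 fell and 6 were not called, or 0 higher and 31 lower adjusted over the list alone, camera adjusted p = 3.62e-31), among them SPINT2, a protease inhibitor (56.4-fold). Mesenchymal cytoskeleton and adhesion genes rose: 19 rose, 1 fell and 11 were not called (19 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.21e-06), with the endocytic adaptor DAB2 up 23-fold and CDH11, a cadherin of mesenchyme, up 12.6-fold. Extracellular matrix genes rose (20 rose, 4 fell and 11 were not called, or 20 higher and 4 lower adjusted over the list alone, camera adjusted p = 5.97e-08), COL5A1 by 36.1-fold. Matrix proteases and inhibitors rose as a group (11 rose, 4 fell and 5 were not called, or 12 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0101), with ADAM19 up 17.6-fold and MMP7 down 27.7-fold. In the EMT transcription factor list, 6 rose, 4 fell and 9 were not called (6 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.572). ZEB2 rose 9.52-fold, and SNAI2 fell 8.98-fold from a lacZ level of 11.04 to 7.88, near the parental 8.12. The dimmer ZEB2 probe went from 6.18 ± 0.22 in lacZ to 7.03 ± 0.06 in SNAIL cells. Lung differentiation genes fell (1 rose, 6 fell and 17 were not called, or 1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0162), including the lineage factors FOXA1 (31.2-fold) and NKX2-1 (6.44-fold) and NAPSA (30.2-fold).

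ERBB receptors and ligands fell on balance in SNAIL cells, as 3 rose, 9 fell and 3 were not called (3 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.0111), with ERBB3 down 29.6-fold and TGFA, a ligand of EGFR, down 28.2-fold. The log2 change of ERBB3 ran from -5.56 to -2.05 over the alternatives. The ERBB call ended against parental cells (adjusted p = 0.0896). ERK pathway output fell (3 rose, 14 fell and 5 were not called, or 3 higher and 15 lower adjusted over the list alone, camera adjusted p = 0.00122). The ERK phosphatase gene DUSP6 fell 2.73-fold, while EPHA4 rose 4.99-fold. Sterol and fatty acid synthesis fell without a riser, as 0 rose, 14 fell and 5 were not called (0 higher and 16 lower adjusted over the list alone; camera adjusted p = 4.3e-08). INSIG1, a sensor of sterols, fell 3.54-fold and the reductase gene DHCR7 3.34-fold. NRF2 targets fell (2 rose, 10 fell and 2 were not called, or 2 higher and 10 lower adjusted over the list alone, camera adjusted p = 1.76e-05), AKR1B10 by 24.3-fold and AKR1C3 by 9.85-fold, both aldo-keto reductases. Hypoxia and glycolysis fell by the preset test (3 rose, 10 fell and 6 were not called, or 3 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.0154; adjusted p = 0.147 with an estimated correlation), although the glucose transporter gene SLC2A3 rose 25.9-fold; the oxygen sensor EGLN3 fell 3.93-fold. The hypoxia call also ended with genes above the median probe alone (adjusted p = 0.0528) and against parental cells (adjusted p = 0.211). YAP/TEAD targets rose by the preset test (12 rose, 2 fell and 9 were not called, or 12 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0048; adjusted p = 0.101 with an estimated correlation), with CCN2 up 13.1-fold, the transcription factor FOXF2 up 9.21-fold and IGFBP3 down 6.04-fold. The NF-kB and cytokine list fell on balance (6 rose, 13 fell and 7 were not called, or 6 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.0291). That NF-kB call ended under settings given below. The neutrophil chemokine CXCL5 fell 16.4-fold while CCL2 rose 22.5-fold.

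Camera called 13 lists after SNAIL, and 11 held with an estimated correlation. The others follow. TGF-beta/SMAD targets gave 9 rose, 14 fell and 10 were not called (10 higher and 15 lower adjusted over the list alone, camera adjusted p = 0.219), with ID1, a target of BMP signalling, down 3.71-fold. Beta-catenin/TCF targets gave 9 rose, 3 fell and 7 were not called (11 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0715), with the feedback gene AXIN2 up 6.62-fold and the secreted Wnt inhibitor DKK1 up 3.86-fold. Bypass receptor kinases gave 9 rose, 11 fell and 13 were not called (9 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.572), with the receptor genes AXL and PDGFRB up 24-fold and 20.6-fold and FGFBP1 down 23.1-fold; the median of 0.07 and mean of 0.0032 were positive and the test pointed down. The BCL2 family gave 3 rose, 6 fell and 7 were not called (3 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.193), with BIK down 13-fold and anti-apoptotic BCL2 up 3.24-fold. Proliferation genes gave 7 rose, 11 fell and 22 were not called (8 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.282). RRM2, of nucleotide synthesis, fell 2.43-fold, MCM4, of the replicative helicase, 2.02-fold, and the mitotic gene CENPF rose 1.84-fold. Stress genes gave 6 rose, 11 fell and 7 were not called (6 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.0715). ASNS, which makes asparagine, fell 4.34-fold and TRIB3 3.14-fold.

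Interferon response genes gave 17 rose, 10 fell and 9 were not called (17 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.178), with OAS2 and OASL of the oligoadenylate synthetase family up 6.72-fold and 6.53-fold, and MHC class I genes gave 5 rose, 5 fell and 4 were not called (6 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.854), with HLA-B up 2.52-fold and PSMB8 down 2.33-fold. Against parental cells OAS2 and HLA-B were lower in SNAIL cells (log2 -1.55 and -0.40). Against parental cells the list medians were -1.33 (adjusted p = 2.5e-13) and -0.47 (adjusted p = 0.00294) in SNAIL cells, so that both signs turned with the control. Haematopoietic markers gave 2 rose, 0 fell and 12 were not called (2 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.506), CD14 up 3.06-fold and CD3D up 1.29-fold. Against parental cells CD14 did not pass (log2 0.008, adjusted p = 0.972). The CD3D call ended without lacZ array 2 or SNAIL array 1 or 3 (adjusted p from 0.0891 to 0.108). Endothelial markers gave 1 rose, 0 fell and 9 were not called (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.806), the one being TIE1 (1.36-fold up; adjusted p = 0.675 with the floor), and neuroendocrine markers 1 rose, 0 fell and 8 were not called (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.282), the one being SCG2 (15.7-fold up). Reference transcripts gave 0 rose, 5 fell and 7 were not called (0 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.229). GUSB fell 1.43-fold and SDHA 1.38-fold (adjusted p = 0.0751 and 0.0503 with the floor). The NF-kB call ended with genes above the median probe alone (adjusted p = 0.0719) and without normalization between arrays (adjusted p = 0.0971). The VIM call in SNAIL cells ended without normalization (log2 0.40, adjusted p = 0.118).

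shCDH1 against shNT cells asks what changed with the hairpin that lowers CDH1. The labels name no second CDH1 hairpin. Effects of the hairpin on other targets, or of the history of these cells, cannot be told from those of the CDH1 loss. The 10 largest falls include DEFB4A, a beta-defensin, at 142-fold (log2 -7.15 ± 0.10; closely related gene copies share its sequence), LCN2 132-fold, SFTA2, a surfactant-associated protein, 103-fold, and NAPSA 89.8-fold. MAL2 fell 97.7-fold and AGR2, a disulfide isomerase of mucus-secreting cells, 67.3-fold. Among the genes that rose, PLAC8 rose 60.7-fold (log2 5.92 ± 0.15), the decoy receptor IL13RA2 49.7-fold, ALDH1A1, which makes retinoic acid, 47.8-fold, the homeobox gene MSX1 35.1-fold, and CALB2 29.6-fold. CLDN2, a claudin of leaky epithelia, rose 25.9-fold and CDH2 25.1-fold. Of 20046 genes, 6803 were called (33.9%), 3589 higher and 3214 lower, and 1630 changed by at least 1 log2 unit; the share higher was 52.8%, and 63.1% of 3384 with a floor and log2 alone, which moved the all-gene median by 0.12.

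Epithelial lists fell beyond CDH1 itself. Of 36 identity and keratin genes, 1 rose, 27 fell and 8 were not called (1 higher and 30 lower adjusted over the list alone; camera adjusted p = 2.74e-26), with MUC1 down 66.7-fold. Of 23 junction genes, 0 rose, 16 fell and 7 were not called (0 higher and 16 lower adjusted over the list alone; camera adjusted p = 4.85e-12). The junction list includes CDH1, the target of the hairpin, and was not tested without it. MARVELD3, of tight junctions, fell 16.1-fold and JUP, plakoglobin of adherens junctions and desmosomes, 8.67-fold. Mesenchymal genes rose on the preset test (13 rose, 7 fell and 11 were not called, or 13 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.031; adjusted p = 0.0757 with an estimated correlation), DAB2 by 5.59-fold, and the call ended with genes above the median probe alone (adjusted p = 0.0917) or above the 25th percentile probe (adjusted p = 0.0514). Extracellular matrix genes rose on balance (13 rose, 6 fell and 16 were not called, or 13 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0396): the proteoglycan LUM rose 13.1-fold and SPARC 11.9-fold, and FSTL1, a secreted glycoprotein, fell 11.8-fold; the call ended without shCDH1 array 2 (adjusted p = 0.0572), with genes above the median probe alone (0.0563) and with genes above the 25th percentile probe (0.0568). Beta-catenin/TCF targets rose on the preset test (9 rose, 3 fell and 7 were not called, or 9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0483; adjusted p = 0.11 with an estimated correlation), with the growth factor gene BMP4 up 4.77-fold and TNFRSF19 up 4.54-fold; against parental cells the median was -0.008 (adjusted p = 0.243), and the adjusted p was 0.0591 without shNT array 1 and 0.139 against all 3 control groups. EMT transcription factors gave 6 rose, 0 fell and 13 were not called (6 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0561). SOX9 rose 8.78-fold and ZEB1 3.12-fold. The factor list passed without shCDH1 array 1 or shNT array 2 or 3 (adjusted p from 0.0427 to 0.0497). Lung differentiation genes gave 3 rose, 4 fell and 17 were not called (3 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0561). FOXA1 fell 36.1-fold and NKX2-1 17.3-fold. This list passed without shCDH1 array 1 (adjusted p = 0.0494) or shNT array 3 (adjusted p = 0.0427).

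Immune and inflammatory lists fell in shCDH1 cells. In the NF-kB and cytokine list, 1 rose, 19 fell and 6 were not called (1 higher and 20 lower adjusted over the list alone; camera adjusted p = 5.15e-15). CXCL5 fell 63-fold, CXCL1, another neutrophil chemokine, 21.8-fold, and IL6 13.4-fold. In the interferon list, 0 rose, 25 fell and 11 were not called (0 higher and 27 lower adjusted over the list alone; camera adjusted p = 2.61e-15). IFI27 fell 19.4-fold and BST2, which tethers virions, 10.6-fold. MHC class I genes fell (1 rose, 7 fell and 6 were not called, or 1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00344), HLA-B by 14.7-fold and PSMB8 by 3.26-fold. Hypoxia and glycolysis genes fell without a riser (0 rose, 14 fell and 5 were not called, or 0 higher and 16 lower adjusted over the list alone, camera adjusted p = 2.04e-09), the glycolytic regulator PFKFB4 by 5.98-fold and SLC2A3 by 5.19-fold. NRF2 targets rose, as 11 rose, 1 fell and 2 were not called (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.54e-06). AKR1C2 rose 22-fold and AKR1B10 5-fold, while ABCC3 fell 3.07-fold. The AKR1C2 call held under all alternatives, but its log2 change ran from 0.83 to 5.08 over them. With an estimated correlation 8 of the 10 lists called in shCDH1 cells kept their calls, these 5 among them.

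The other lists gave no camera call in shCDH1 cells. Matrix proteases gave 5 rose, 6 fell and 9 were not called (5 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.452), with MMP7 down 49.1-fold and the urokinase receptor PLAUR down 9.78-fold. TGF-beta/SMAD targets gave 8 rose, 11 fell and 14 were not called (8 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.604). CCN2 rose 18.1-fold and the cell cycle inhibitor CDKN1A fell 2.68-fold; the median was -0.06, the mean 0.02, and the test pointed down. ERBB receptors and ligands gave 4 rose, 5 fell and 6 were not called (4 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.397). ERBB3 fell 27.1-fold (log2 from -5.09 to -2.08 over the alternatives) and TGFA 11.5-fold. ERK pathway output gave 11 rose, 5 fell and 6 were not called (11 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.302), with IER3, an early response gene, down 5.94-fold and the phosphatase DUSP4 up 3.19-fold, which against parental cells was not called (log2 0.42, adjusted p = 0.0731). Bypass receptor kinases gave 9 rose, 8 fell and 16 were not called (9 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.761). AXL rose 14.7-fold and FGFBP1 fell 5.41-fold. The BCL2 family gave 4 rose, 7 fell and 5 were not called (4 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.435), with pro-apoptotic BMF down 6.51-fold and BCL2 up 2.97-fold. YAP/TEAD targets gave 9 rose, 5 fell and 9 were not called (10 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.397). The coagulation factor gene F3 fell 6.27-fold. Proliferation genes gave 10 rose, 8 fell and 22 were not called (10 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.435), with the mitotic kinase PLK1 up 1.96-fold and MKI67 down 1.74-fold. The MKI67 call ended against parental cells (log2 -0.115, adjusted p = 0.551) and with the floor (adjusted p = 0.0692).

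Stress genes gave 7 rose, 7 fell and 10 were not called (8 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.672) in shCDH1 cells, ATF3, a stress-induced factor, rising 2.46-fold and the cystine transporter SLC7A11 2.16-fold. Sterol and fatty acid synthesis gave 3 rose, 8 fell and 8 were not called (4 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.302). SQLE rose 2.04-fold and HMGCS1 fell 1.94-fold, both enzymes of cholesterol synthesis. Haematopoietic markers gave 2 rose, 0 fell and 12 were not called (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.435), namely CD68 (1.56-fold up) and CD14 (1.28-fold up). The CD14 call ended without shCDH1 array 2 or shNT array 2 or 3 (adjusted p from 0.0645 to 0.107), and against parental cells the change was -0.24 (adjusted p = 0.138). No endothelial marker was called, as 0 rose, 0 fell and 10 were not called (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.855). Neuroendocrine markers gave 2 rose, 0 fell and 7 were not called (2 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.397), namely DLL3 (3.1-fold up) and SCG2 (2.22-fold up), with a median of -0.02, a mean of 0.29 and a test pointing up. Reference transcripts gave 1 rose, 3 fell and 8 were not called (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.577). SDHA fell 2.1-fold; their median was 0.02, their mean -0.10, and the test pointed down.

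**Figure D2:**
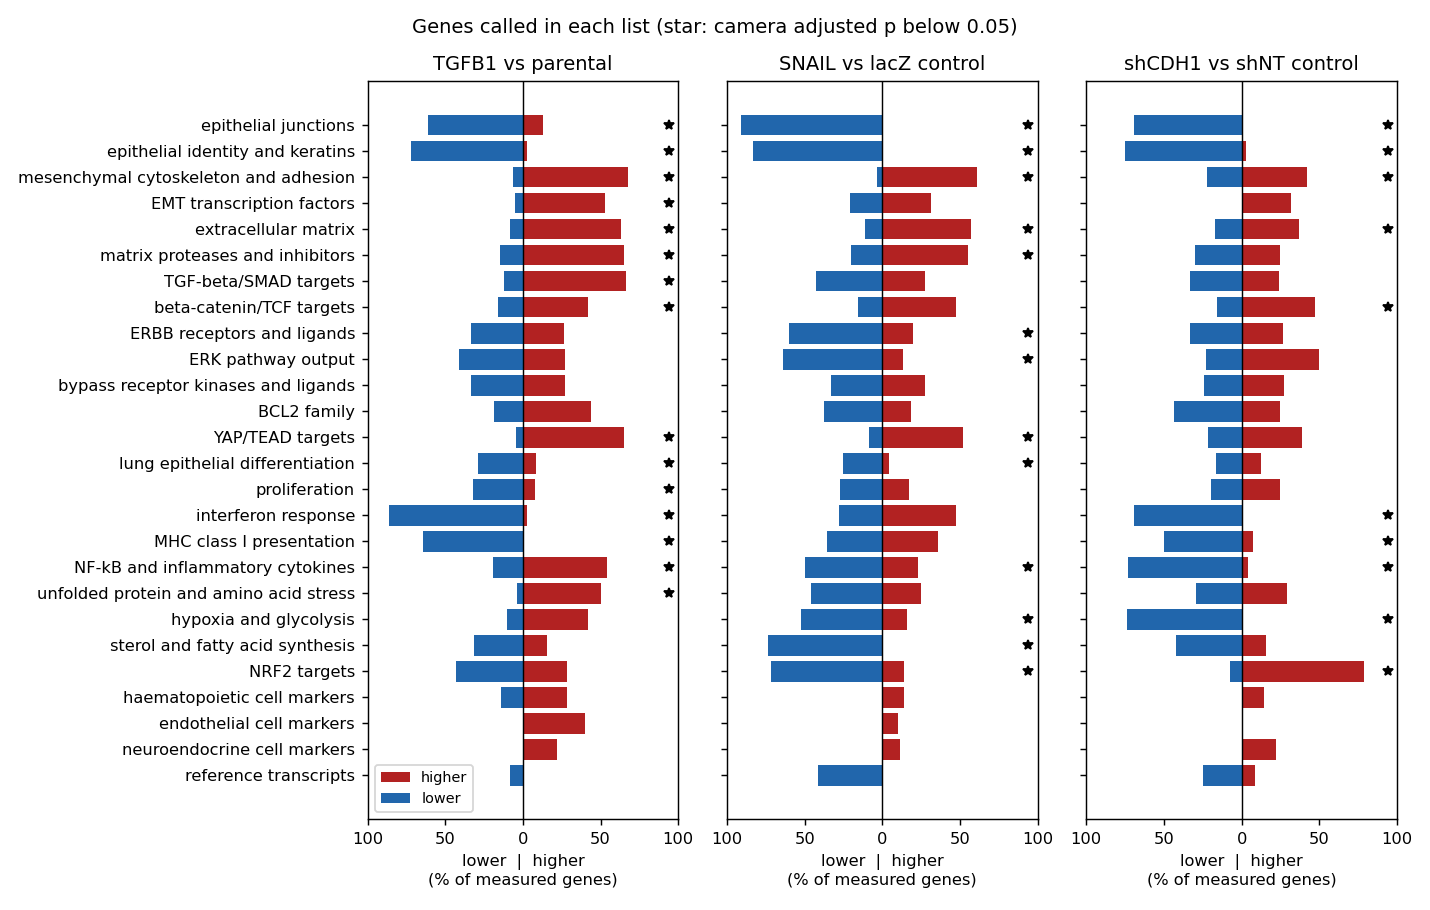
Percentage of the measured genes of each of the 26 lists (y axis) called higher (red, right) or lower (blue, left; x axis, percent) in the 3 main comparisons; a star marks a camera adjusted p below 0.05. The epithelial lists fall in all 3 comparisons, and NRF2 targets are lower in SNAIL cells (10 of 14) and higher in shCDH1 cells (11 of 14).

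Differences between routes were tested as differences of effects. The losses of CDH1 differed: the TGFB1 effect stood above the SNAIL effect by 5.27 ± 0.17 log2 units and above the shCDH1 effect by 4.05 ± 0.17. Effects differed at 5873 genes between TGFB1 and SNAIL, 6042 between TGFB1 and shCDH1, and 6404 between SNAIL and shCDH1. Camera called 14, 13 and 10 of the 26 lists for these differences, and 9, 10 and 8 of those held with an estimated correlation. Epithelial junction genes fell less under TGFB1 than in SNAIL cells (median difference 1.03, camera adjusted p = 1.79e-13) or in shCDH1 cells (0.38, camera adjusted p = 1.48e-05). TGF-beta/SMAD targets stood higher under TGFB1 than in SNAIL cells (0.78, camera adjusted p = 5.79e-09) and in shCDH1 cells (0.83, camera adjusted p = 4.74e-07). NF-kB and cytokine genes were higher under TGFB1 than in shCDH1 cells for 21 of 26 genes (median 1.49, camera adjusted p = 4.82e-19). The NRF2 target effect was lower in SNAIL than in shCDH1 cells for 13 of 14 genes (median -1.46, camera adjusted p = 1.79e-13), and the sterol list was lower in SNAIL cells too (-0.71, camera adjusted p = 0.000125). Extracellular matrix genes rose more in SNAIL than in shCDH1 cells (0.33, camera adjusted p = 0.000377).

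A common part of the response was shared. In all 3 comparisons 723 genes rose and 847 fell, where independent sets of these sizes would share 108.7 and 85.9. These expected numbers take all 20046 genes as equally likely to be called. Genes near background may be called less often, and independent sets would then share more. Without normalization between arrays, 28.7% of the 887 shared genes were higher in place of 46.1%. The largest shared losses were of PRODH, a proline-degrading enzyme (49.5-fold, 35.9-fold and 73.8-fold in the TGFB1, SNAIL and shCDH1 comparisons), NAPSA, MMP7 and AGR2 (22.6-fold and 41.7-fold in the first pair). SPINK1, a trypsin inhibitor, fell 22.1-fold, 22.6-fold and 32.7-fold, and SOX2 fell 20-fold in SNAIL and 65-fold in shCDH1 cells as well. HTRA1 was the one riser among the top 10, up 54.9-fold in SNAIL and 16.5-fold in shCDH1 cells. Across genes, which are not independent replicates, effects correlated at r = 0.416 (rho = 0.301) for TGFB1 with SNAIL, 0.395 (0.211) for TGFB1 with shCDH1 and 0.445 (0.241) for SNAIL with shCDH1.

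Some genes went opposite ways. IL6 rose under TGFB1 and fell in shCDH1 cells, a difference of 8.31 ± 0.15 log2 units, and SRPX did so by 8.33 ± 0.15. Against parental cells the fall of SRPX in shCDH1 cells was not called (log2 -0.23, adjusted p = 0.0966). CST6, a protease inhibitor, rose 6.86-fold under TGFB1 and fell 29.6-fold in SNAIL and 28.5-fold in shCDH1 cells. CXCL5 rose 2.66-fold under TGFB1 (log2 0.070, adjusted p = 0.701, against shNT cells) and fell in both others. The cadherin gene CDH6 rose 18.6-fold under TGFB1 and 7.91-fold in shCDH1 cells but fell 7.49-fold in SNAIL cells, from a raised lacZ level (log2 -0.11, adjusted p = 0.617, against parental cells). SLC2A3 differed most between SNAIL and shCDH1 cells, by 7.07 ± 0.19. Opposite calls numbered 944 for TGFB1 with SNAIL (1144 if independent), 1084 for TGFB1 with shCDH1 (1060 if independent) and 1225 for SNAIL with shCDH1 (1241 if independent). The expected numbers again take all genes as equally likely to be called, so they may be too low.

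Control viruses against parental cells show the background of the hairpin and SNAIL comparisons. Interferon response genes were lower with both viruses: 35 of 36 fell and none rose in lacZ cells (median -1.43, camera adjusted p = 5.08e-59), and 33 fell and none rose in shNT cells (median -1.33, camera adjusted p = 1.85e-48). Group means of the list were 11.17 ± 0.07 (SD, n = 3) in parental, 10.29 ± 0.21 in TGFB1, 9.49 ± 0.13 in lacZ, 9.89 ± 0.04 in SNAIL, 9.65 ± 0.02 in shNT and 8.32 ± 0.06 in shCDH1 cells. Genes below were chosen after their values were seen. In lacZ cells IFI27 and OAS2 of the interferon list changed by -5.37 and -4.30 log2 units, DEFB4A by -5.01 and the keratin gene KRT20 by -4.36, while the secreted glycoprotein gene OLFM4 rose by 5.20, SPP1 by 4.18 and CDH2 by 4.20. In shNT cells OAS2 changed by -4.61, KRT20 by -3.83 and HOPX by -3.16, while SPP1 rose by 3.67, EPDR1 by 2.63 and OLFM4 by 2.58. Camera called 11 of 26 lists in lacZ cells and 8 in shNT cells, of which 10 and 3 held with an estimated correlation. Counts of called genes were 2760 (13.8%; 1412 higher and 1348 lower) and 4161 (20.8%; 2035 higher and 2126 lower); the share higher in shNT cells went from 48.9% to 29.9% with median centring and 18.3% without normalization, where the all-gene median was -0.10.

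Mesenchymal cytoskeleton and adhesion genes were already raised in lacZ cells (18 rose, 2 fell and 11 were not called, or 19 higher and 2 lower adjusted over the list alone, camera adjusted p = 8.82e-15) and in shNT cells (14 rose, 3 fell and 14 were not called, or 14 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.000102). The NF-kB and cytokine list moved apart: it fell in lacZ cells (2 rose, 14 fell and 10 were not called, or 3 higher and 17 lower adjusted over the list alone, camera adjusted p = 7e-13) and rose in shNT cells (10 rose, 3 fell and 13 were not called, or 11 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00203). MHC class I genes fell in lacZ (0 rose, 7 fell and 7 were not called, or 0 higher and 9 lower adjusted over the list alone, camera adjusted p = 7.49e-08) and, by the preset test, in shNT cells (2 rose, 5 fell and 7 were not called, or 3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00259; adjusted p = 0.0504 with an estimated correlation). Lung differentiation genes fell in lacZ (2 rose, 6 fell and 16 were not called, or 2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.000191) and, by the preset test, in shNT cells (1 rose, 6 fell and 17 were not called, or 1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0272; adjusted p = 0.0504 with an estimated correlation). ERK pathway output fell in lacZ (0 rose, 8 fell and 14 were not called, or 0 higher and 9 lower adjusted over the list alone, camera adjusted p = 4.04e-05) and, by the preset test, in shNT cells (2 rose, 8 fell and 12 were not called, or 2 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.021; adjusted p = 0.0504 with an estimated correlation). In lacZ cells epithelial identity genes fell (2 rose, 13 fell and 21 were not called, or 2 higher and 14 lower adjusted over the list alone, camera adjusted p = 3.49e-05), and extracellular matrix (8 rose, 2 fell and 25 were not called, or 9 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00148), YAP/TEAD (10 rose, 1 fell and 12 were not called, or 12 higher and 1 lower adjusted over the list alone, camera adjusted p = 8.4e-07) and sterol genes (8 rose, 0 fell and 11 were not called, or 9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00172) rose. TGF-beta/SMAD targets rose there by the preset test (8 rose, 7 fell and 18 were not called, or 9 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0466; adjusted p = 0.135 with an estimated correlation). In shNT cells proliferation genes fell (1 rose, 16 fell and 23 were not called, or 2 higher and 18 lower adjusted over the list alone, camera adjusted p = 0.000168; adjusted p = 0.0504 with an estimated correlation) and hypoxia genes rose (6 rose, 0 fell and 13 were not called, or 6 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0172; adjusted p = 0.162 with an estimated correlation) by the preset test.

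**Figure D3:**
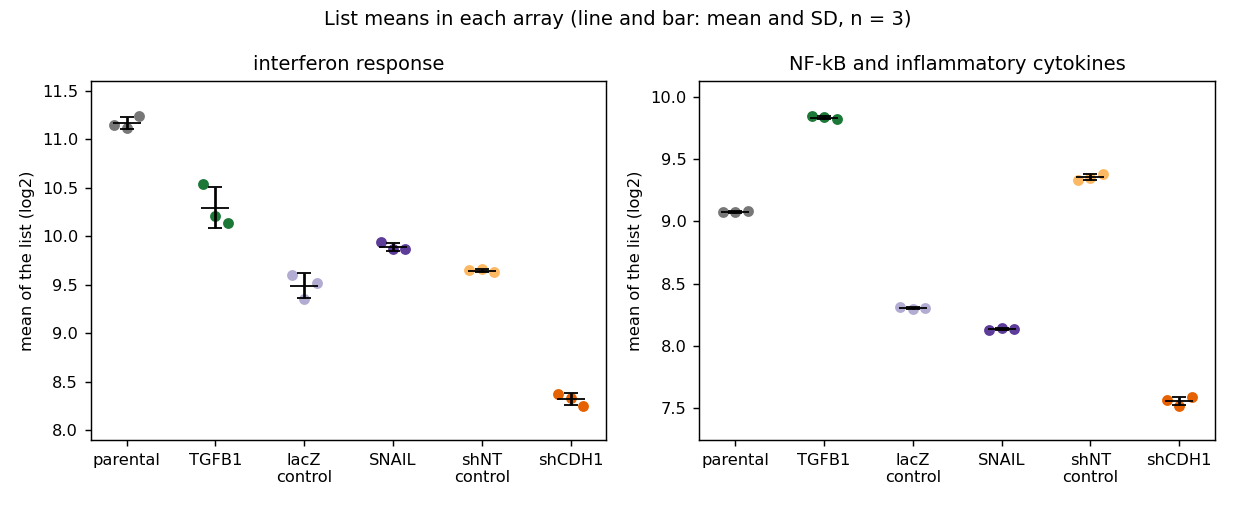
Mean normalized log2 intensity of the interferon list and of the NF-kB and cytokine list (y axes) in each array, by group (x axis); points are arrays, lines and bars the mean and SD of 3 arrays. Parental arrays are highest for the interferon list (11.17), and the NF-kB list is highest under TGFB1 (9.84) and lowest in shCDH1 cells (7.55).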

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

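The tests of the lacZ pattern, of the SNAI1 probe and of the parental culture were chosen after the result was seen. Those of the interferon list by scaling and by single arrays are recorded as written before. The design planned list tests for the main comparisons and named no fall of the interferon list in the virus controls.

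The change from parental cells differed between the lacZ and shNT viruses for VIM by 2.41 log2 units (adjusted p = 4.54e-14) and for CDH2 by 2.38 (adjusted p = 5.18e-15), higher in 3 of 3 lacZ arrays, and it differed for 4374 of 20046 genes. RNA of SNAIL cells in the lacZ arrays would bring all genes that SNAIL cells raise, yet over the 74 genes at least 4 log2 units above parental in SNAIL cells the median share of the rise present in lacZ cells was 0.94% (upper quartile 4.21%), where VIM and CDH2 need 67.0% and 52.1%. For RNA of TGFB1 cells the median over 36 genes was 1.80% (upper quartile 9.88%), against needs of 71.9% and 64.4%. RNA of shCDH1 cells, where VIM and CDH2 are high too, was not tested as a source. Labels taken from the SNAIL, TGFB1 or shCDH1 group are argued against too, because 3 of 3 lacZ arrays were closest to their own group and, outside it, to shNT arrays (r = 0.986, 0.985 and 0.989). An exchange of the whole lacZ group with the parental or shNT group could give the same result, so it was not tested. A response to the lacZ virus, or another culture history of these cells, may account for the levels and was not tested, since 1 set of lacZ arrays is all the design has. The lacZ and shNT viruses also differ in vector (pLX303 and pLKO1), which cannot be told apart from their other differences.

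The interferon list was lower in both virus groups than in parental cells, a difference between groups in the direction opposite to the antiviral response that a virus often evokes. Scaling between arrays is argued against, as the weakest list median over median centring, no normalization and the floor was -1.35, and so is a single parental array, as the weakest median without one of them was -1.32. A culture state of the parental cells that raised these genes may be the source instead of the virus. The 2 cannot be told apart, because the weaker of the medians, -1.33, rests on the only parental arrays.

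The SNAI1 probe was not higher in the cells named for it, although their CDH1 loss was 49-fold. An exchange of the SNAIL and lacZ labels is argued against, if SNAIL is taken to repress junction genes: the junction list's median against parental cells was 0.0062 in arrays labelled lacZ and -1.72 in arrays labelled SNAIL. The virus may make a transcript that lacks the part the probe binds. This cannot be told from the difference of -0.14, since the position of the probe was not used here.

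Probes without a single gene symbol were outside the report's comparisons, and some changed with the groups: 1954 of 17208 were called under TGFB1, 2053 in SNAIL and 1970 in shCDH1 cells.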

How the results depend on the processing

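Results under control groups not planned, without normalization, with the design's floor and log2, with offset 16, with median centring or left-out arrays for lists, and the same for shared genes, differences and control viruses were chosen after seeing the data; the others were planned. Of the results for named genes under all alternatives, 5253 kept their side of the threshold without turning while called, 71 lost the call, 1 gained it and 14 turned while called as reported or under the alternative; for lists the numbers were 1255, 29, 57 and 8. Of the counts, 271 stayed within 1.5 times and 31 did not; the planned second quantile normalization changes nothing, since the values are already quantile normalized. Signal over background limits what can be seen: 33.2% of probes lay below their array's median on every array, and 12935 genes had a mean above the median probe.

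Counts outside 1.5 times were as follows. With every probe as a unit, more units are tested: 9676 under TGFB1, 11390 in SNAIL, 10763 in shCDH1, 6632 for shNT against parental, and 9277 and 9769 for the differences of shCDH1 from TGFB1 and from SNAIL. A log2 change of at least 1, by construction, left 1460, 2029 and 1630 in the main comparisons, 471 for lacZ and 421 for shNT, 2143, 2051 and 2429 for the differences (TGFB1 and SNAIL, TGFB1 and shCDH1, SNAIL and shCDH1) and 351 shared. The floor and log2 without normalization gave 3599 in SNAIL, 3384 in shCDH1, 711 for lacZ, 1652 for shNT, 2999 and 2830 for the differences of SNAIL from TGFB1 and shCDH1, and 659 shared; no normalization gave 4641, 4208, 1091, 1946, 3624 (SNAIL and shCDH1) and 887. The cause was not tested. Shares of higher genes among the differences went from 48.0%, 49.8% and 53.0% to 27.8%, 19.4% and 43.0% without normalization and 26.2%, 13.1% and 35.8% with the floor. Fry, which does not compare with other genes, called 25, 23 and 23 lists where camera called 15, 13 and 10.

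With 1 array left out, where the group left with 2 is assumed to vary like the others, the counts ranged from 5376 to 5874 (TGFB1), 6591 to 6865 (SNAIL), 6039 to 6832 (shCDH1), 2182 to 2471 (lacZ), 2995 to 4567 (shNT), 5390 to 5664, 5422 to 6252 and 5904 to 6562 (differences), and 1450 to 1595 (shared), and called lists from 15 to 16, 13 to 13 and 9 to 12. The replicate block of title numbers kept 99.5% to 99.6% of the calls, and arrays sharing a description number as a random block correlated at 0.043. Averaging arrays that share a description number leaves 12 values and kept 83.8%, 88.6% and 87.1% of the calls under TGFB1, in SNAIL and in shCDH1 cells. It kept 74.6% for lacZ and 74.3% for shNT, and 84.7%, 81.3% and 85.3% for the differences. Fewer calls held under other settings. The floor kept 60.4%, 48.9% and 49.6% in the main comparisons, 25.7% for lacZ, 39.1% for shNT and 50.3%, 60.0% and 44.0% for the differences. No normalization kept 65.9%, 63.1%, 61.7%, 39.5%, 46.0%, 64.2%, 65.8% and 56.3% in the same order. Against lacZ cells 64.3% of the TGFB1 calls held and 138 turned, and against shNT cells 73.4% held and 131 turned. Against parental cells 83.1% of the SNAIL calls held and 96 turned, and 68.9% of the shCDH1 calls held and 121 turned.

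The medians of 11, 7 and 10 lists under TGFB1, in SNAIL and in shCDH1 cells changed sign with median centring, no normalization or the floor; 3, 0 and 0 of these were lists called as reported. With the floor the hypoxia list under TGFB1 had a median of -0.11 (adjusted p = 0.0297), the NRF2 list under TGFB1 -0.26 (adjusted p = 0.0397) and the lung list in shCDH1 cells 0.10 (adjusted p = 0.000505). The interferon list in SNAIL cells went to -0.026 without normalization (adjusted p = 0.0311) and -0.087 with the floor (adjusted p = 0.0131). These camera tests compare a list with the other genes, and they kept their reported directions. They pointed up for the hypoxia and interferon lists and down for the NRF2 and lung lists. With the floor the all-gene median was -0.28 under TGFB1, 0.12 in shCDH1 and -0.096 in SNAIL cells. Without normalization it was -0.037 in SNAIL cells. Among results called as reported or under the alternative, the direction of list tests and of named genes turned with the control alone in the settings run, except for SCG3 under TGFB1, which is dim and gave -0.042 with the floor. In place of parental, lacZ cells gave TGFB1 medians of 0.0565 for lung differentiation, 0.63 for interferon and 0.0898 for MHC class I, and log2 changes of 0.37 for HOPX, 1.60 for IFITM1, 1.25 for MX2, 0.75 for HLA-B, 0.90 for CCL20 and 0.11 for CD14. shNT cells gave 0.62 for the interferon list, 0.61 for MX2, 1.02 for HLA-B and -0.34 for SLC2A3, and all 3 control groups together gave 0.14 for the interferon list and 0.26 for HLA-B. For SNAIL cells, parental cells as control gave -1.33 for the interferon list, -0.47 for MHC class I, -1.55 for OAS2 and -0.40 for HLA-B, and all 3 control groups -0.47 for the interferon list. For shCDH1 cells, parental cells gave -0.24 for CD14. These follow from the levels of the control groups. Under TGFB1, SNAI1 was called with median centring (0.40, adjusted p = 0.0445; over all its alternatives the change ran from -0.12 to 0.56), and HOPX was not with offset 16 (-0.27, adjusted p = 0.488), where another probe is the brightest. Other calls of named genes and lists that ended under a scaling, control or left-out array stand in the report or are in the totals above; the cause was not tested.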

Other observations

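The gene families below, and their tests, were chosen after the result was seen; the counts of splits were planned.

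Clustered histone genes, whose products package DNA, rose in SNAIL cells. Of 72, 40 were higher and 1 lower (median 0.47; camera adjusted p = 5.3e-10, adjusted p = 0.0514 with an estimated correlation), with H2BC11 up by 2.88 log2 units, H2AC19 by 2.66 and H2BC8 by 2.37. The histone median was 0.50 with median centring, 0.44 without normalization and 0.22 with the floor. In shCDH1 cells the test of histones pointed down, with 2 higher and 16 lower (median -0.056, 0.085 with the floor; camera adjusted p = 0.0385, adjusted p = 0.335 with an estimated correlation). In shCDH1 cells 8 of 15 MHC class II genes, which present antigen to helper T cells, were lower and 0 higher (median -0.54; camera adjusted p = 0.000462, adjusted p = 0.0844 with an estimated correlation), HLA-DMB changing by -4.17, and the median was -0.15 with the floor. The same family rose with the shNT virus against parental cells, with 7 higher and 0 lower (median 0.36; camera adjusted p = 0.000214, adjusted p = 0.134 with an estimated correlation), and the median was 0.07 with the floor. Of 31 serpins, protease inhibitors, 11 were lower and 1 higher in shCDH1 cells (median -0.15, 0.06 with the floor; camera adjusted p = 0.00236, adjusted p = 0.0844 with an estimated correlation), SERPINB3 changing by -5.06. Metallothioneins, which bind metals, rose under TGFB1: 6 of 9 were higher and 0 lower (median 0.67, 0.19 with the floor; camera adjusted p = 0.00322, adjusted p = 0.248 with an estimated correlation), MT1G by 2.13. In shNT cells 2 of these were higher and 0 lower (median 0.19, -0.018 with the floor; camera adjusted p = 0.0346, adjusted p = 0.269 with an estimated correlation). Of 23 claudins, 7 were lower and 2 higher in SNAIL cells (median -0.10 as reported and -0.16 with the floor; camera adjusted p = 0.0143, adjusted p = 0.0514 with an estimated correlation). The S100 family was called with a test pointing down in shCDH1 (median -0.26, 0.0048 with the floor; camera adjusted p = 0.0204) and lacZ cells (median -0.070, -0.065 with the floor; camera adjusted p = 0.0295). So was the CEACAM family in shCDH1 (median -0.11, 0.078 with the floor; camera adjusted p = 0.0432) and lacZ cells (median 0.028, -0.014 with the floor; camera adjusted p = 0.0295). Ephrins and their receptors were called in lacZ cells alone (median -0.16, -0.14 with the floor; camera adjusted p = 0.0353). Over 18 families and the 5 comparisons of groups 13 camera calls were made, and 0 held with an estimated correlation. Members of these families are alike in sequence, so a probe can bind several of them.

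The labels were set against other splits of the same arrays. For the 5 comparisons of 2 groups there are 10 splits, too few for a share under 0.05; 1 split, the real one, gave as many genes, with 6245 called under TGFB1 (highest other 0), 7340 in SNAIL (0), 6803 in shCDH1 (373), 2760 for lacZ (0) and 4161 for shNT (0). For the differences of effects, 1 of 100 splits, the real one, gave as many as 5873 (highest other 3188), 6042 (2916) and 6404 (3687) genes. That cannot exclude chance for a difference of effects, because the splits mix the groups and do not make the effects equal. The arrays exchanged may also come from one culture. For the 1570 genes shared by all 3 comparisons 1 of 100 splits, the real one, gave as many and the highest other was 0. This does not test the sharing, because the other splits of the TGFB1 and SNAIL comparisons call 0 genes by themselves.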
